A study of Mus musculus with 6 samples.

How the data were processed

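Polyadenylated RNA from livers of C57BL/6J mice was sequenced from strand-specific TruSeq libraries, 3 from wild-type mice (WT) and 3 from mice heterozygous for Ptprd (Ptprd+/-, here Het), per the labels. The kind of altered Ptprd allele, the sex, age and diet of the mice and the time of day at which livers were taken are not given in the sources used here. The series design counts 3 liver samples per genotype, and if any of them shared a mouse the p-values would measure only technical spread.

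The authors deposited a table of read counts per Ensembl gene with 1 column per library. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.10, STAR 2.5.3a, HTSeq 0.6.1p1 and DESeq2 1.16.1 were used with genome build mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The count columns, raw per the file headers, hold whole numbers for 25904 genes, each with a gene name, mm10 coordinates, a biotype and Gene Ontology terms. The normalized columns of the same table were not used, because decimal marks had been changed in them. The authors' deposited table of differential expression gives a log2 fold change, a p-value and an adjusted p-value per gene for WT over Het, per the file headers. Its log2 fold changes were turned to Het over WT here. The unit of that table was read from its headers and values, since its decimal commas and column marks kept it from an automatic unit check.

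Total counts ranged from 37924266 to 72954187 per library. Genes with too few counts were removed with edgeR's filterByExpr, which left 14606 genes holding 99.955% of all counts. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are scaled to the effective library size. Het was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes in the text are those of this fit, with standard errors taken from the quasi-likelihood F statistic. Because 3 against 3 libraries make 10 splits, an exact permutation test of a single gene cannot give a two-sided p below 0.1.

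Before the data were examined, 41 gene lists were fixed for hepatic metabolism, stress responses, nuclear receptor targets, sex bias, the circadian clock and the cell types a liver sample can hold. The 37 lists with at least 4 tested members were tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the genes. Its p-values can then rise without any correlation between members, so a call lost there is weak evidence against a list. A preset correlation of 0.01 understates the correlation of co-regulated genes, so list calls that it alone gives carry less weight. Genes within 10 Mb of Ptprd were compared with all other tested genes by Fisher's exact test (two-sided). The share of genes at an unadjusted p under 0.05 was used there, because fewer than 5 genes passed edgeR's adjusted threshold. It was kept in the settings where more genes passed, so that 1 choice changed at a time.

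Genes were named by a rule fixed before the data were examined. It took Ptprd and, in each direction, the 12 genes with the largest fold change among those past the adjusted threshold with a mean of at least 1 CPM, a gene symbol that is not a predicted Gm or Rik name, and all Het libraries on one side of all WT libraries. Where fewer than 5 passed, it was filled to 5 by smallest unadjusted p. It further took 2 members of each list, and 2 genes near Ptprd, by smallest unadjusted p where none passed. Of the genes it took, 1 is not reported here. Other genes named in the text were chosen after their values were seen, and this is said where they appear.

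The tests were tried on simulated data first, with counts for the 14606 genes drawn from the means, dispersions and library sizes of these samples and 50 genes changed at each of 4 sizes. At 2-fold, edgeR called 86% of the changed genes and DESeq2 90%, and at 1.5-fold 20% and 40%. Of unchanged genes, edgeR called 9, limma-voom 10 and DESeq2 32. In a second simulation both of the lists moved 1.5-fold were called by camera, with 1 other list. Simulated genes were drawn independently of each other, while the correlations estimated in the samples were 0.11 to 0.73 for the called lists. The simulation therefore does not show how often camera makes false calls in these samples.

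Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, DESeq-type (RLE) and upper-quartile scaling, no filter, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library, other thresholds and windows of 5 and 20 Mb. Added after seeing the data were a robust fit, edgeR's newer quasi-likelihood method, a clock score as a covariate, and a fit without 2 libraries whose clock genes stood apart. The clock score is the mean log2 CPM of Dbp, Tef, Per3, Nr1d1, Nr1d2 and Ciart minus that of Arntl, Npas2, Clock, Cry1 and Nfil3, genes picked after their values were seen. Gene length and GC content were taken from the longest GENCODE vM21 transcript of each gene. Camera was also run on 2805 Gene Ontology terms of 10 to 200 tested genes, as the deposited table lists them, after the fixed lists had been seen.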

Results

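Liver messenger RNA was measured in 3 Ptprd+/+ (WT) and 3 Ptprd+/- (Het) mouse samples. Ptprd encodes receptor-type protein tyrosine phosphatase delta, and the title of the series places the gene in the metabolic disease of the liver. The comparison asks what the loss of 1 copy changes in the liver transcriptome. Total counts were 45849269, 48526395 and 37924266 in WT 1, WT 2 and WT 3, and 38918379, 47054020 and 72954187 in Het 1, Het 2 and Het 3. Every pair of libraries differed by more than sampling noise. The biological coefficient of variation across genes was 18.5%. Values below are CPM as mean ± SD with n = 3 per genotype, and fold changes are Het over WT with the standard error (SE) on the log2 scale.

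Ptprd itself was measured first. The gene (ENSMUSG00000028399) lies on chromosome 4 at 75941238 to 78211961 (mm10). It had 129 ± 2.49 CPM in WT and 65.2 ± 12.1 CPM in Het (SD, n = 3), a log2 fold change of -0.99 (SE 0.14), or 1.98-fold lower in Het. The Het libraries had 54.1, 78.1 and 63.4 CPM, all below the lowest WT library at 127 CPM, so each library's Ptprd level matched its genotype label. With edgeR's quasi-likelihood test and adjustment over all genes its adjusted p was 0.298, and with DESeq2 it was 2.86e-06. The exact permutation p for 3 against 3 was 0.1, the smallest that this design allows.

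**Figure D1:**
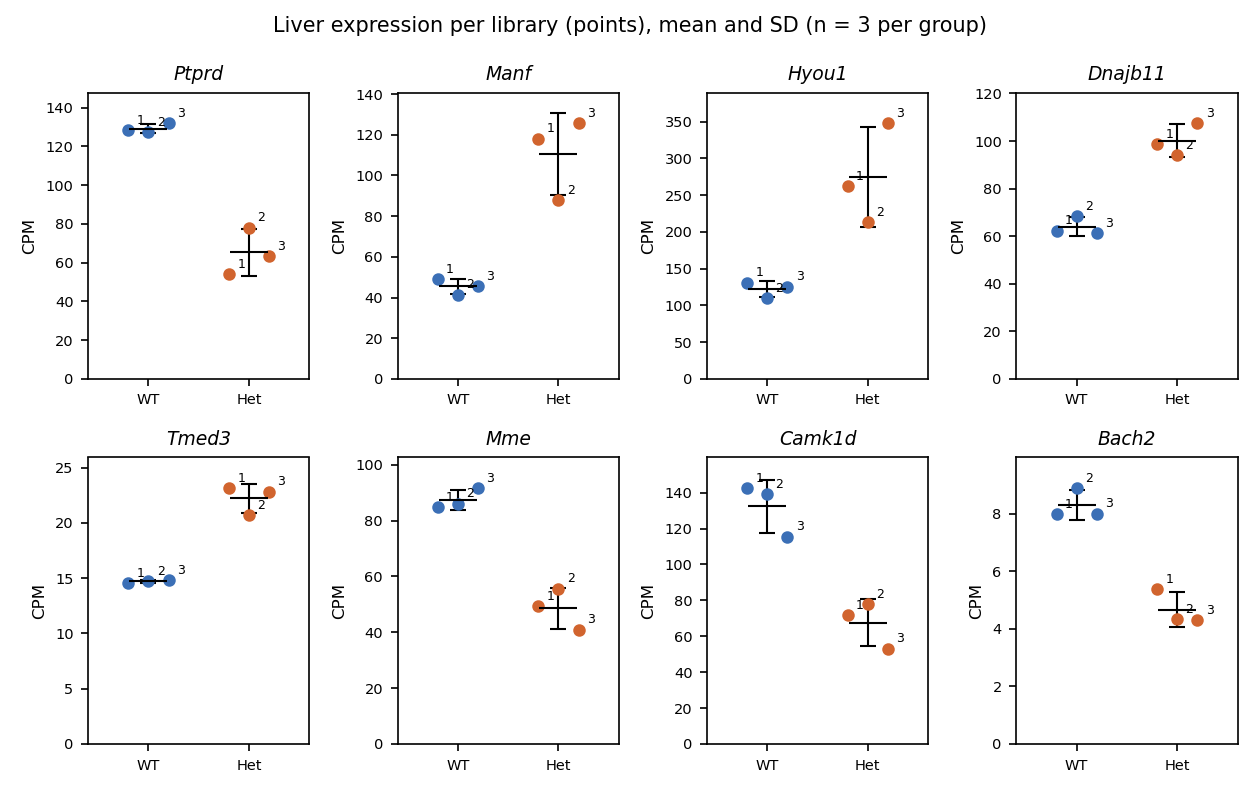
CPM (vertical axes, from 0) of Ptprd and 7 of the other genes with the smallest p, per genotype. Points are libraries numbered by replicate, and bars give the mean and SD (n = 3). In each panel the 3 Het libraries lie on one side of the 3 WT libraries; Ptprd was 1.98-fold lower and Manf 2.43-fold higher in Het.

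Apart from Ptprd, genes that separated the genotypes clearly included endoplasmic reticulum (ER) chaperones and cofactors on the higher side. None passed edgeR's adjusted p of 0.05, where the smallest adjusted p was 0.298. Manf, an ER-resident secreted stress protein, had 45.4 ± 3.83 CPM in WT and 111 ± 19.98 CPM in Het, 2.43-fold higher. Hyou1, an ER chaperone of the HSP70 family, was 2.25-fold higher, and Dnajb11, a cochaperone of BiP, was 1.56-fold higher at 64.0 ± 3.91 against 100.1 ± 6.87 CPM. Tmed3, which acts in transport between the ER and the Golgi, was 1.51-fold higher, and Ptma, which encodes prothymosin alpha, was 1.70-fold higher. Ptma has many processed pseudogene copies that can take its reads, so its level is uncertain. On the lower side, Mme, which encodes the peptidase neprilysin, was 1.80-fold lower at 87.5 ± 3.65 against 48.6 ± 7.39 CPM. Camk1d, a calcium- and calmodulin-dependent kinase gene, was 1.96-fold lower, and Bach2, a transcription repressor gene, was 1.78-fold lower. The DESeq2 adjusted p values of these 8 genes lay between 3.55e-10 for Manf and 0.00301 for Tmed3.

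Over all 14606 tested genes, edgeR's quasi-likelihood test called 0 genes at an adjusted p of 0.05, with 495 higher and 550 lower in Het at an unadjusted p under 0.05. Limma-voom also called 0, with 1071 at an unadjusted p under 0.05. DESeq2 called 61, of which 30 were higher and 31 lower, but in the simulation it called 32 unchanged genes, against 9 for edgeR. Without a filter on low counts edgeR called 73, of which 45 were also called by DESeq2. By the authors' deposited table, 59 genes had an adjusted p under 0.05, 30 of them higher in Het and 29 lower. All 59 had the same sign in the edgeR fit, an unadjusted p under 0.05 there and no overlap between the genotypes. They were selected on the counts of these same libraries, so this is no independent support. In all, 2025 tested genes (13.9%) had non-overlapping genotypes, where chance gives 10% on average over splits. The first principal component held 32.6% of the variance and set WT 1 against Het 1 and Het 3, with Het 2 among the WT libraries.

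Of the 37 gene lists tested, 9 were called by camera with its preset correlation, 5 higher and 4 lower in Het, and 0 with an estimated correlation or with fry. The unfolded protein and integrated stress response was the list with the smallest p. Its members had a median log2 fold change of 0.58, 16 of the 17 tested members were higher in Het, and in 12 all Het libraries lay above all WT libraries. Besides Manf and Hyou1, Hspa5, which encodes the main ER chaperone BiP, was 1.78-fold higher, Creld2 2.66-fold and Sdf2l1 2.80-fold, with Hspa5 at 702, 591 and 632 CPM in WT and 1128, 965 and 1336 CPM in Het. These 3 genes were chosen after their values were seen. The members tied to the integrated stress response, also chosen afterwards, differed among themselves. Trib3, Ddit3 and Chac1 had log2 fold changes of 1.17, 0.82 and 0.59, and Atf4 and Sesn2 of 0.05 and -0.11. By edgeR 0 members passed over all genes and 11, all higher, passed when adjusted over the list alone, and DESeq2 called 7. Camera gave an adjusted p of 8.14e-14 with the preset correlation. With an estimated correlation of 0.15 between members the p was 0.0097 and the adjusted p = 0.359. Fry gave an adjusted p of 0.0582 for a shift one way and 0.017 in its mixed test, which counts members that move either way.

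The heat shock list, cytosolic chaperones for the most part, was higher as well, with a median log2 fold change of 0.43 and 10 of 11 members higher. Without Het 3 the median was 0.18. Hsph1 was 1.79-fold higher (46.7 ± 7.78 against 83.4 ± 25.4 CPM) and Hspa8 1.45-fold. The list had an adjusted p of 5.32e-04 by camera, and an adjusted p = 0.829 with an estimated correlation. By edgeR 0 members passed over all genes and 1 when adjusted over the list alone. In a fit without Het 2 and Het 3, added after seeing the data, its adjusted p was 0.0523.

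**Figure D2:**
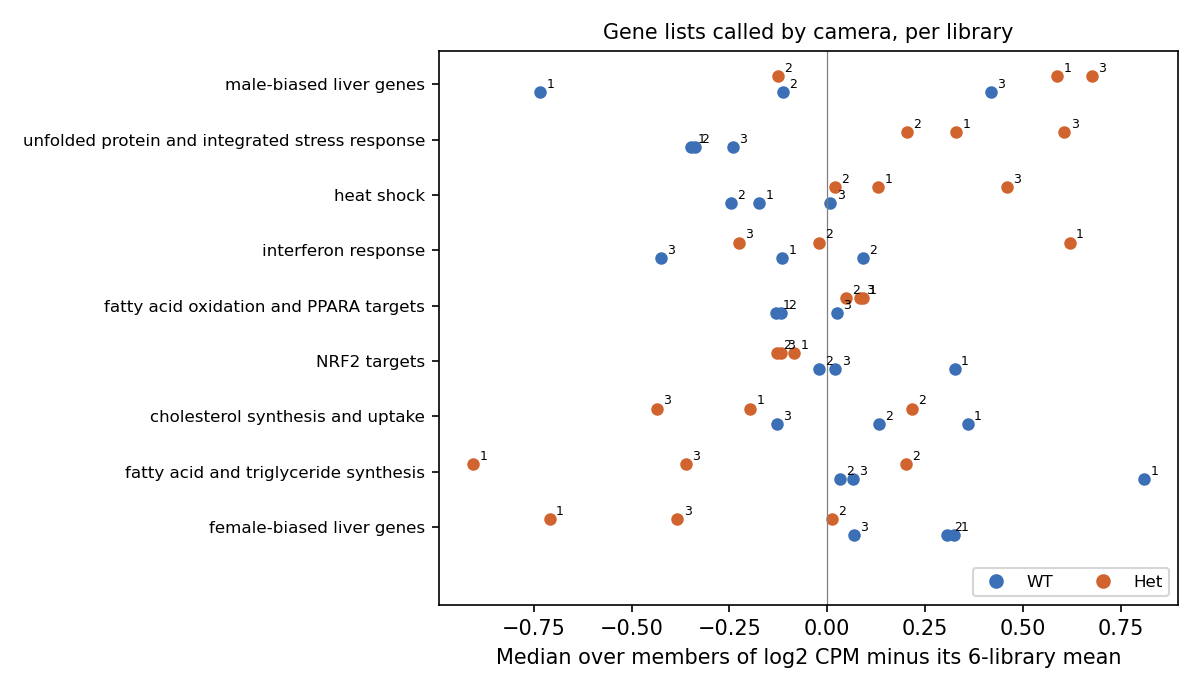
Level of the 9 gene lists called by camera in each library, as the median over members of log2 CPM minus the gene's mean over the 6 libraries (horizontal axis). Points are libraries numbered by replicate, WT in blue and Het in orange. For the unfolded protein and integrated stress response list the Het libraries lie at 0.203 to 0.606 and the WT libraries at -0.347 to -0.242, while for interferon response Het 1 lies apart at 0.619.

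Genes of fatty acid and triglyceride synthesis were lower in Het 1 and Het 3, while Het 2 lay within the WT range. Differences between libraries of one genotype were large. The list's level was taken as the median over members of log2 CPM minus the gene's mean over all libraries. It was 0.809, 0.032 and 0.066 in WT 1, WT 2 and WT 3, and -0.905, 0.202 and -0.361 in Het 1, Het 2 and Het 3. The list's median log2 fold change was -0.56, 14 of 18 members were lower and 6 had an unadjusted p under 0.05. In 4 members all Het libraries lay below all WT libraries. Pnpla3, a lipid droplet acyltransferase and lipase gene, had 32.7 ± 25.2 CPM in WT and 4.08 ± 2.37 CPM in Het, 7.91-fold lower, a log2 fold change of -2.98 that was -2.14 without WT 1. Acacb, the acetyl-CoA carboxylase that regulates mitochondrial fatty acid entry, was 2.25-fold lower at 260 ± 57.6 against 115 ± 54.5 CPM. Scd1, the stearoyl-CoA desaturase, chosen after its values were seen, had 21540, 3886 and 8320 CPM in WT and 1382, 3248 and 3714 CPM in Het. Srebf1 and Dgat2, also chosen afterwards, had log2 fold changes of 0.09 and 0.18. By edgeR 0 members passed over all genes and 2 passed when adjusted over the list alone, and DESeq2 called 2. Camera gave the list an adjusted p of 5.32e-04, and an adjusted p = 0.829 with an estimated correlation. Without WT 1 the median was -0.17 and camera's adjusted p 0.0539, so the call rested on that library. Without Het 1 the median was -0.33, and over all settings it ranged from -1.43 to -0.17.

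Cholesterol synthesis and uptake had a median log2 fold change of -0.20 with 18 of 21 members lower. Pmvk, phosphomevalonate kinase, was 1.75-fold lower (110.5 ± 11.3 against 63.2 ± 22.8 CPM), and Acat2 was 1.29-fold lower. The list's adjusted p was 0.0082 by camera, and adjusted p = 0.829 with an estimated correlation. The call ended without WT 1 (median -0.09, adjusted p 0.273) and without Het 3 (median -0.09, adjusted p 0.487), while the median was -0.32 without WT 3 and -0.50 without Het 2. Fatty acid oxidation and PPARA targets had a median of 0.17, with 16 of 23 members higher, and its members moved both ways. Ech1, an enzyme of peroxisomal and mitochondrial fatty acid oxidation, was 1.32-fold higher, while Pdk4, the kinase that inhibits pyruvate dehydrogenase, was 4.06-fold lower (20.6 ± 9.86 against 5.12 ± 1.89 CPM) with a DESeq2 adjusted p of 5.18e-06. Camera gave an adjusted p of 0.0401, and an adjusted p = 0.829 with an estimated correlation, while fry's mixed test gave an adjusted p of 0.0144. Camera's call ended when any 1 of 5 libraries was left out, namely WT 1, WT 2, Het 1, Het 2 or Het 3, with adjusted p values up to 0.273, and also with no filter on low counts (0.0679), with the clock score as a covariate (0.0652) and without both Het 2 and Het 3 (0.0883).

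**Figure D3:**
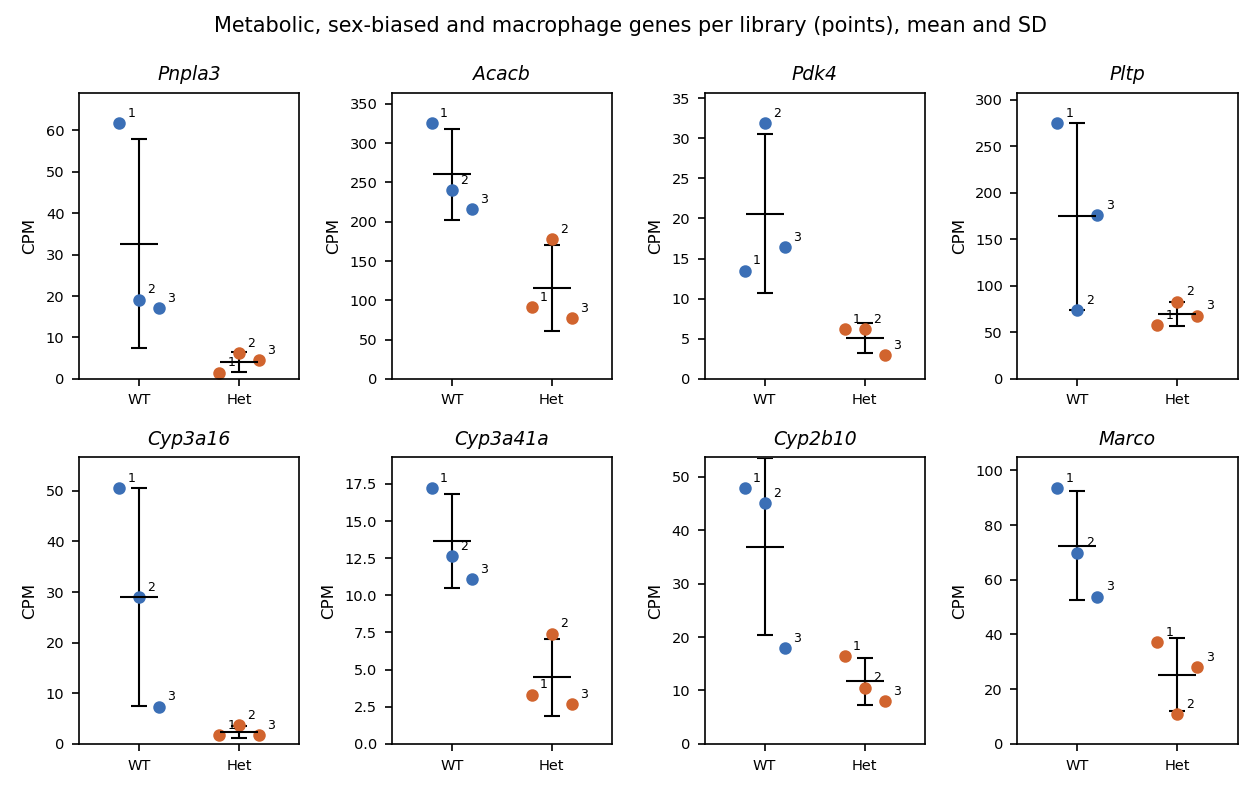
CPM (vertical axes, from 0) of 8 genes of lipid metabolism, sex-biased and xenobiotic cytochromes and macrophages, per genotype. Points are libraries numbered by replicate, and bars give the mean and SD (n = 3). Pnpla3 ranges widely among WT libraries (32.7 ± 25.2 CPM) and is low in all Het libraries (4.08 ± 2.37 CPM).

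Sex-biased liver genes moved in opposite directions, mainly in Het 1 and Het 3. Of the 16 female-biased genes 15 were lower in Het, with a median log2 fold change of -0.59. In 5 members all Het libraries lay below all WT libraries. The list's level was 0.324, 0.307 and 0.069 in WT 1, WT 2 and WT 3. It was -0.709, 0.013 and -0.383 in Het 1, Het 2 and Het 3, so Het 2 lay close to WT 3. Cyp3a16 had 29.0 ± 21.6 CPM in WT and 2.39 ± 1.14 CPM in Het, 12.2-fold lower, a log2 fold change of -3.605 that was -2.94 without WT 1. Cyp3a41a had 13.7 ± 3.17 against 4.48 ± 2.58 CPM, 3.06-fold lower. These cytochromes have near-identical paralogs, so their single values are uncertain. Camera gave an adjusted p of 2.34e-05, and an adjusted p = 0.768 with an estimated correlation. By edgeR 0 members passed over all genes, 6 passed when adjusted over the list alone, and DESeq2 called 2. Of the 13 male-biased genes 11 were higher, with a median of 0.85 (adjusted p 0.0082 by camera, adjusted p = 0.829 with an estimated correlation). Among them Cyp2u1 was 1.89-fold higher and Mup20, a major urinary protein gene, 1.80-fold. In 2 members all Het libraries lay above all WT libraries. The male-biased level was -0.733, -0.113 and 0.419 in WT 1, WT 2 and WT 3. It was 0.587, -0.125 and 0.677 in Het 1, Het 2 and Het 3, so Het 2 lay within the WT range. The male-biased call ended without WT 1 (median 0.42, adjusted p 0.273), without Het 1 (0.0683), without Het 3 (median 0.54, adjusted p 0.0629) and without both Het 2 and Het 3 (0.0521). All 6 libraries carried the X-linked Xist at 273 to 479 CPM, and the Y-linked Ddx3y had at most 1 count in any library.

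The interferon response list had a median log2 fold change of 0.25 with 17 of 18 members higher. Isg15 was 1.63-fold and Usp18 1.61-fold higher. Camera gave an adjusted p of 0.0082, and an adjusted p = 0.829 with an estimated correlation. Without Het 1 the median was 0.03 and camera's adjusted p 0.794, and without WT 3 they were 0.135 and 0.264. Without Het 3 the median was 0.41, and over all settings it ranged from 0.03 to 0.66. NRF2 targets had a median of -0.14 with 13 of 14 members lower. Hmox1, heme oxygenase, was 1.75-fold lower and Nqo1 1.49-fold. The adjusted p was 0.0343 by camera, and adjusted p = 0.829 with an estimated correlation, and the call ended without WT 1 (median -0.05, adjusted p 0.273), Het 2 (0.152) or Het 3 (0.0867), without both Het 2 and Het 3 (0.395) and with the clock score as a covariate (0.218). Without Het 1 the median was -0.23.

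The lists closest to insulin and glucose control were not called. Insulin signalling had a median log2 fold change of -0.02 (adjusted p 0.955 by camera), gluconeogenesis -0.11 (0.804), glycolysis and glucose uptake -0.03 (0.904) and glycogen metabolism -0.15 (0.159). G6pc, the catalytic subunit of glucose-6-phosphatase, had 509 ± 52.5 CPM in WT and 320.2 ± 105.2 CPM in Het (edgeR adjusted p 0.685), and Pck1 had 2635 ± 190.7 and 3314 ± 919 CPM. Trib3, a pseudokinase gene counted among the insulin signalling and the stress response lists, was 2.26-fold higher with a DESeq2 adjusted p of 0.015. STAT3 signalling and targets had a median of 0.04 (adjusted p 0.332), with Socs3 at 6.95 ± 2.58 against 14.0 ± 8.56 CPM (log2 fold change 1.03, and 0.41 without Het 3) and Junb 1.78-fold higher (DESeq2 adjusted p 0.0119). The tyrosine phosphatases other than Ptprd had a median of 0.00 (adjusted p 0.361), with Ptpn9 1.42-fold and Ptprj 1.34-fold lower. Lipoproteins had a median of 0.05 (0.565), with Pltp 2.51-fold lower. Lipid droplets and lipid uptake had -0.18 (0.565), bile acid synthesis and transport -0.09 (0.49, with Cyp7a1 1.49-fold lower), and the acute phase response 0.06 (0.843).

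Markers of other liver cells did not pass either. Kupffer cells and macrophages had a median log2 fold change of -0.12 (adjusted p 0.147 by camera), although Marco, a macrophage scavenger receptor, had 72.4 ± 19.9 CPM in WT and 25.4 ± 13.3 CPM in Het. Infiltrating leukocytes had a median of -0.24 (0.159), stellate cells and fibrosis -0.13 (0.247), sinusoidal endothelial cells -0.10 (0.722), cholangiocytes 0.02 (0.72) and erythroid cells -0.42 (0.641). Pericentral hepatocyte genes had 0.11 (0.361) and periportal genes -0.13 (0.66). Of the lists for tissues near the liver, fewer than 4 members were expressed, 1 of exocrine pancreas (Cela2a), 1 of skeletal muscle (Mylpf) and 2 of adipocytes (Lipe and Car3), and these were not tested as lists. Of the sex chromosome list 1 member, Xist, was tested. Among the remaining lists, nuclear-encoded oxidative phosphorylation had a median of 0.06 (0.0689), mitochondrially encoded genes -0.18 (0.0689), cell cycle 0.16 (0.0787) and ribosomal proteins 0.08 (0.188). The liver tumour and fetal list had -0.11 (0.505), growth hormone and STAT5 targets -0.14 (0.843), immediate early genes -0.06 (0.659), AHR targets -0.16 (0.544) and CAR and PXR targets -0.01 (0.544), with Cyp2b10 3.18-fold lower. Where members moved both ways, camera's direction was opposite to the sign of the median for the tyrosine phosphatase, acute phase, insulin, glycolysis, cholangiocyte, immediate early and circadian lists. Its direction was opposite to the sign of the mean for the lipoprotein, immediate early, circadian and acute phase lists. Mitochondrial transcripts took 4.49, 4.26 and 3.76% of counts in WT and 3.16, 3.35 and 4.28% in Het.

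Circadian clock genes divided the Het libraries among themselves. The list as a whole was not called (median log2 fold change 0.21, adjusted p 0.843 by camera). Dbp, a clock output transcription factor, had 129 and 122 CPM in Het 2 and Het 3, against 13.5 CPM in Het 1 and 18.9, 29.6 and 14.4 CPM in WT. Arntl, which encodes the core activator BMAL1, ran the other way, with 2.41 and 1.92 CPM in Het 2 and Het 3, against 21.4 CPM in Het 1 and 17.2, 11.8 and 19.7 CPM in WT. Both genes were chosen after their values were seen. Clock was 1.58-fold lower in Het, with 31.3 CPM in Het 1 and 20.2 and 20.3 CPM in Het 2 and Het 3. The clock score was 0.89, 1.51 and 0.26 in WT, -0.13 in Het 1, and 4.29 and 4.42 in Het 2 and Het 3 (log2 units). In a fit without Het 2 and Het 3, which assumes that the lone Het library varies like the others, edgeR called 0 genes and camera 10 lists. With the score as a covariate edgeR called 0 genes and camera 12 lists, among them the circadian list, from whose members the score is built.

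**Figure D4:**
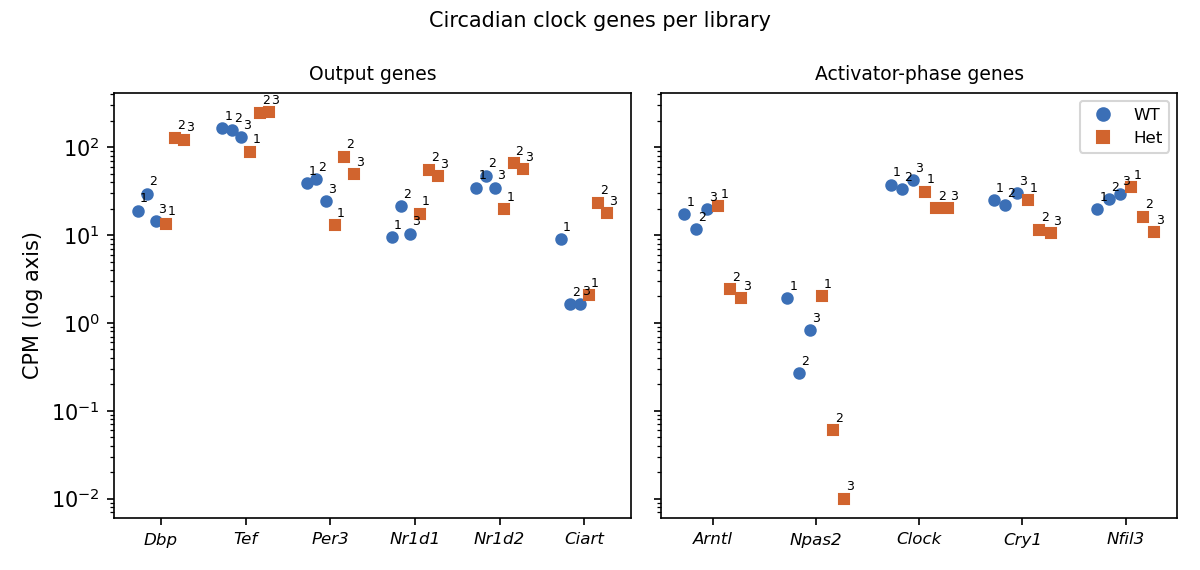
CPM (vertical axis, logarithmic) of clock genes in each library, with circles for WT and squares for Het, numbered by replicate. The left panel holds 6 output genes and the right panel 5 activator-phase genes. Het 2 and Het 3 stand above the other 4 libraries for Dbp (129 and 122 CPM) and below them for Arntl (2.41 and 1.92 CPM).

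Genes that neighbour Ptprd on chromosome 4 showed no excess of differences. Within 10 Mb of the gene 2 of 34 tested genes had an unadjusted p under 0.05 (5.88%), against 1042 of 14571 elsewhere (7.15%). The odds ratio was 0.81 with a 95% interval of 0.094 to 3.19, and Fisher's exact test gave p = 1. The interval is wide, and an odds ratio of up to 3.19 was not excluded. The 2 genes were Adamtsl1, at 1.43 ± 0.38 against 0.76 ± 0.23 CPM, and Ccdc171, at 6.11 ± 1.08 against 4.47 ± 0.71 CPM.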

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

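The robust fit, edgeR's newer quasi-likelihood method, the clock covariate and the fit without both Het 2 and Het 3 were chosen after seeing the data. The cause was not tested for any change given here unless one is named. Ptprd was lower in Het under every setting, with log2 fold changes of -1.13 to -0.87 when single libraries were left out, and passed the threshold with DESeq2 (-0.985) and with no filter (-0.98, adjusted p 5.88e-04) alone. The number of genes called was 0 in most settings, 61 with DESeq2, 73 with no filter, and 0 to 1 when single libraries were left out (Manf without Het 2). Without the filter the prior degrees of freedom of the dispersions rose from 4.17 to 20.2, which gives every gene a firmer error, and 72 of the 73 genes were among those tested with the filter. Of 84 other named genes 19 passed with DESeq2 and 21 with no filter. The number of lists called was 4 (without WT 1) to 11 when single libraries were left out, 0 with an estimated correlation, 0 with fry and 8 to 13 otherwise. In data simulated at these depths edgeR and limma-voom called 20% of 1.5-fold changes and DESeq2 40%. EdgeR called 86% of simulated 2-fold changes but neither Ptprd (1.98-fold) nor Manf (2.43-fold) in the samples, so the simulated share does not carry over to these genes.

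The labels number the samples 1 to 3 in each genotype. Same-numbered samples deviated together with correlations of -0.068, 0.116 and 0.152 and did not all correlate best with their own number, so the numbers were not taken as pairs. With the replicate number as a block edgeR called 0 genes and camera 8 lists, fatty acid oxidation had an adjusted p of 0.062, the odds ratio near Ptprd was 1.64, and Car3 had a log2 fold change of -1.58e-04.

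Called lists are given with their adjusted p. The stress response and female-biased lists kept their call in 15 of 17 settings, fatty acid synthesis and heat shock in 14, cholesterol and interferon in 13, male-biased in 11, NRF2 in 10 and fatty acid oxidation in 6. With an estimated correlation the values were 0.359 for stress response, 0.768 for female-biased and 0.829 for the other 7. With fry they were 0.0582 for stress response, 0.648 for female-biased, heat shock, NRF2 and fatty acid oxidation, and 0.756 for fatty acid synthesis, cholesterol, interferon and male-biased, and the uncalled glycolysis list changed sign (0.972). Fatty acid oxidation was at 0.0679 with no filter and 0.0652 with the clock covariate, which left NRF2 at 0.218. Without both Het 2 and Het 3, NRF2 was at 0.395, fatty acid oxidation 0.0883, heat shock 0.0523 and male-biased 0.0521. When single libraries were left out, fatty acid synthesis ranged from 3.84e-06 to 0.0539, cholesterol from 5.47e-06 to 0.487, fatty acid oxidation from 0.00918 to 0.273, male-biased from 2.15e-05 to 0.273, NRF2 from 0.00151 to 0.273 and interferon from 5.05e-05 to 0.794.

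Other lists gained a call in some settings. Nuclear-encoded oxidative phosphorylation did with DESeq2 (0.0087), limma-voom (0.0246), the clock covariate (5.11e-04) and without both (8.59e-04). Mitochondrially encoded genes did with DESeq2 (0.015) and limma-voom (0.0479), cell cycle (0.015) and Kupffer cells (0.0214) with DESeq2, and ribosomal proteins with the clock covariate (1.59e-04) and without both (2.12e-04). Lipoproteins (0.0343) and the circadian list (0.027) did with the clock covariate, and sinusoidal endothelial cells (median -0.33) without both. The circadian call carries no weight, because the clock score is built from members of that list.

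Some lists turned direction. The acute phase list became higher and passed with the clock covariate (0.00156) and without both (2.96e-05), as did infiltrating leukocytes without both (0.00391). The other turns did not pass. With DESeq2 they were acute phase (0.682) and circadian (0.79), and with no filter acute phase (0.90). With the clock covariate they were CAR and PXR and erythroid (0.978), Kupffer and insulin (0.82), cholangiocytes and liver tumour (0.943), growth hormone and periportal (0.797) and leukocytes (0.45). Without both they were CAR and PXR and cholangiocytes (0.921), Kupffer (0.59), growth hormone and periportal (0.682), insulin (0.698) and liver tumour (0.899). The odds ratio near Ptprd crossed 1 without passing, at 1.08 with DESeq2, 1.20 with no filter, 1.16 in the 20 Mb window, 1.02 with the clock covariate, 1.35 without both, and 0 to 1.29 when single libraries were left out.

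Leaving out single libraries gave some other lists a call, with adjusted p from 0.0257 to 0.604 for glycogen, 1.15e-04 to 0.92 for acute phase, 0.00207 to 0.502 for cell cycle, 0.00282 to 0.773 for Kupffer cells and 5.14e-05 to 0.773 for leukocytes. The range was 0.0226 to 0.88 for erythroid cells, 0.00148 to 0.654 for oxidative phosphorylation, 0.00132 to 0.578 for mitochondrially encoded genes and 2.42e-04 to 0.633 for ribosomal proteins. Lists that were called in none of these fits changed direction only, with adjusted p from 0.372 to 0.903 for gluconeogenesis, 0.273 to 0.99 for glycolysis, 0.54 to 0.915 for insulin signalling, 0.111 to 0.844 for lipid droplets and 0.0922 to 0.922 for lipoproteins. For these the range was 0.273 to 0.99 for growth hormone targets, 0.211 to 0.948 for the circadian list, 0.0629 to 0.935 for sinusoidal endothelial cells, 0.525 to 0.99 for cholangiocytes and 0.271 to 0.504 for periportal genes. Log2 fold changes of named genes changed sign. Gapdh went from 0.56 to -0.10 with the clock covariate and -0.40 without both, Flt4 from 0.16 to -0.0584 and -0.21, and Stat5b from -0.23 to 0.0261 without both. Without single libraries they ranged from -0.44 to 0.0245 for Xist, -0.0472 to 0.31 for Flt4, -0.0091 to 0.36 for Krt18, -0.79 to 0.0028 for Hbb-bs, -0.18 to 0.18 for Car3 and -0.36 to 0.0454 for Mylpf.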

Other observations

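The tests of the clock covariate, of mislabelling, of the sex of the livers, of the clock score of Het 1 and of the splits for edgeR and DESeq2 gene counts and for the fatty acid synthesis and female-biased lists were chosen only after the result was seen, as were the Gene Ontology terms described first. Of 2805 terms, camera with the preset correlation called 4, all higher in Het, and 0 with an estimated correlation (adjusted p = 1). The ER chaperone complex came first, with 5 of 10 genes higher at an unadjusted p under 0.05 and 0 lower (adjusted p 7.66e-04). Its estimated correlation was -0.0304, under the preset 0.01, yet camera's unadjusted p rose from 2.73e-07 to 0.00581 with it. Correlation between members was therefore not what ended this call. These related terms did not pass: the ER unfolded protein response (41 genes, median log2 fold change 0.05, adjusted p 0.23), the response to ER stress (65 genes, median 0.07, adjusted p 0.238) and unfolded protein binding (72 genes, adjusted p 0.0824). The other 3 called terms were ribosomal, with the small mitochondrial ribosomal subunit at a median log2 fold change of 0.15 over 27 genes (adjusted p 0.0291, and adjusted p = 1 with an estimated correlation). Genes of antigen binding, most of them immunoglobulin genes, had a median of -0.45 over 19 genes and did not pass (adjusted p 0.0824). Among them Jchain, a plasma cell gene picked after its values were seen, had 5.1, 2.83 and 6.29 CPM in WT and 2.63, 2.38 and 2.23 CPM in Het.

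Fmr1nb, a testis-type gene on chromosome X (68761839 to 68804567, mm10), was found by looking through the genes with the smallest p. It had 17, 74 and 21 counts in the WT libraries and 1, 2 and 2 counts in the Het libraries. The ratio of Het to WT, corrected for library size, was 0.038 with a 95% counting interval of 0.0121 to 0.0915, which covers counting error only. Without WT 2, which holds 74 of the 112 WT counts, it was 0.0695 (0.0213 to 0.177). The edgeR adjusted p was 0.298, and the mean level of 0.792 CPM in WT is low.

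Other splits of the libraries bear on the counts of calls. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For edgeR's gene count the comparison decides nothing, because every split reaches 0. All 10 did, and the highest other split called 1. At an unadjusted p under 0.05 the real split had 1045 genes and the others 371 to 1773. For DESeq2 the real split called 61 genes, 2 of the 10 splits called as many, and the highest other, WT 1, WT 2 and Het 2 against the rest, called 177. A split with several times the real count points to a structure of the libraries other than genotype. Camera called 9 lists for the real split, 7 of the 10 splits called as many, and the highest other called 17. For the fatty acid and triglyceride synthesis list, camera's p was 5.75e-05 in the real split, and smaller in the split of WT 1, WT 3 and Het 2 against the rest (5.03e-10) and in that of WT 1, WT 2 and Het 2 (3.32e-05). For the female-biased list it was 1.26e-06 in the real split and 2.44e-04 in the most extreme other split.

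The higher unfolded protein and stress response list is the first pattern. Its camera p was 2.2e-15 for the real split and 1.92e-04 for the most extreme other split, so 1 of 10 splits reached it, which is too few splits to decide. A trend of fold change with gene length and GC content does not account for it, since removing the trend left a median of 0.517 (95% bootstrap interval over members 0.382 to 1.06). Clock phase was not settled by the covariate fit. With the clock score in the model the median was 0.549 (interval 0.412 to 0.824). The list was still called by camera with its preset correlation. No Het library scored within the WT range of 0.26 to 1.51, so this fit extrapolates and cannot exclude clock phase. The list's level was 0.33 in Het 1, whose score of -0.13 lay below that range. It was 0.203 and 0.606 in Het 2 and Het 3, above that range, and -0.347 to -0.242 in WT. The level thus did not run one way with the score, but only Het 1 lay on the lower side, which does not decide. Both intervals cover the spread over genes, not over livers. The Ptprd genotype and clock phase stay open. So does a difference in feeding, age or handling between genotypes, which no label gives and which was not tested.

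The second pattern is the clock. Wee1, Usp2, Cdkn1a and Elovl3, clock-controlled genes outside the score, were written down before their values were seen, with the direction a later or earlier phase predicts. All 4 had Het 2 and Het 3 outside the other libraries in that direction, as with Usp2 at 50.5 and 50.7 CPM against 15.4 to 42.2 CPM. Wee1 had 23.1 and 22.1 CPM, against at most 16.5 CPM (WT 2). The margin was small for Cdkn1a (4.79 and 3.09 CPM, against 5.57 CPM in WT 2). It was also small for Elovl3 (4.24 and 4.7 CPM, against 5.08 CPM in WT 1), which is in the male-biased list too. A different clock phase, for example from another time of collection, is therefore a candidate explanation. Mislabelled libraries are argued against by Ptprd, whose highest Het level was 78.1 CPM. Genotype alone would place Het 1 with Het 2 and Het 3, and Het 1 did not lie there. That is 1 library, which decides nothing by itself, so the genotype as the reason was not settled. The Het libraries left the WT scores (0.26 to 1.51) in both directions. Het 2 and Het 3 scored 4.29 and 4.42, and Het 1 scored -0.13, below every WT library.

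The third pattern is the lower female-biased list. A mixture of sexes is argued against, since Ddx3y had at most 1 count and Xist at least 273 CPM in every library, so all 6 livers look female. With the clock score in the model the median was -0.895. No Het library scored within the WT range, so this fit does not decide about clock phase. Reads shared between paralogs stay open, since without the Cyp3a and Sult members the median was -0.351 over 10 genes (interval -0.562 to -0.114), a range that reaches past -0.297, the bound set beforehand. Of these 10 genes 9 were still lower (camera p 0.00781 with the preset correlation, not adjusted). This goes against reads shared among the Cyp3a and Sult members as the whole reason, without meeting that bound. The genes left still hold the related Cyp2b9 and Cyp2b13, so they are not free of shared reads. Whether the genotype, hormonal state or age may underlie the rest was not tested.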
